A study of Mus musculus with 5 samples.

How the data were processed

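The data are RNA-seq of mouse tumor macrophages, 3 MEK1-hi and 2 MEK1-low libraries. Per the labels' protocols, RNA was extracted with TRIzol, RNA with an integrity number above 8.0 was taken, stranded poly(A) libraries were made from 750 ng and 100-base paired reads were sequenced to a planned 25000000 per sample. Per the submitters' processing notes, FastQC 0.73, TopHat, Cufflinks, Cuffdiff and the mm10 genome were named, with no role or order. The gene annotation and the strand setting of the counting are not given in the sources used here.

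The authors deposited 1 Cuffdiff table comparing the groups. Its FPKM values are the authors' pooled estimates, 1 per group, and its test statistic is a score deposited by the authors. The p-value and q-value columns are also the authors' as deposited; the q values equal the Benjamini-Hochberg adjustment of the p values over the 12311 rows with status OK, to within rounding. The smallest p is 5e-05, shared by 91 rows, so genes at that value cannot be ranked by p. Of the other rows, 12667 were not tested by Cuffdiff, 2 had too much data and 2 failed. The log2 fold change was computed here from the deposited FPKM values, because 515 cells of the deposited fold change column held spreadsheet error text. The test statistic column held 5 such cells.

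Genes were called with the authors' own test at a q of 0.05. FPKM values are not counts, so no count model was run, and the table has no values per library, so no test could be made from replicates. No standard error was derived from the statistic: Cuffdiff's p values do not match those of a normal distribution. They are smaller in 99.7% of tested rows and larger in some with a large statistic (15 of the called rows), where the smallest p limits them. Depth cannot be read from the table, since low FPKM values showed no whole-read steps, so no interval or detection floor is given.

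Before the data were examined, 36 gene lists with 1082 symbols were fixed, of which 1057 were found, 20 symbols after update through RefSeq synonyms. List tests used 11110 genes: tested rows with 1 symbol, above 0 in both groups and with an FPKM of at least 1 in at least one group, the more abundant row where a symbol was repeated. Each list with at least 5 tested members (34 lists) was compared with all other genes by limma's cameraPR on the test statistic, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists, called at 0.05. An estimated correlation needs values per library, so a preset of 0.05 was run in its place. Fisher's exact test compared the share of called members with the other genes. On simulated data for the MEK1-hi over MEK1-low comparison (11110 genes, 50 draws of shuffled statistics, 6 lists shifted by 1), camera recovered 100% of the shifted lists and called 1.33% of the unshifted ones. Shuffling breaks correlation between genes, so this does not test the preset. Many called lists had mean statistics smaller than the shift of 1, such as 0.58 for ribosomal proteins and 0.31 for type I interferon. Recovery at such sizes was not tested.

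The named genes followed a rule fixed with the lists. It took the 10 largest and 10 smallest log2 fold changes among called genes with 1 symbol, an FPKM of at least 1 in the higher group and above 0 in both. It added the 5 called genes with the largest gain and the 5 with the largest loss of FPKM, in each list up to 4 called members with the largest absolute statistic (or, with none called, up to 2 with the highest mean FPKM), and Map2k1 and Map2k2. The rule gave 102 genes, of which 68 were called, and the text names most of them. Genes named outside the rule are said to be so. Some items are not reported here.

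Alternatives changed the q threshold, the fold threshold, the FPKM filter, the adjustment, the source of p, the treatment of rows with several symbols, the scaling, the pseudocount, and for lists the statistic, the correlation and the ranks. Leaving out each library and a replicate block could not be run. Transcript lengths were the longest per symbol in GENCODE release M21. Coordinates are the authors' loci on mm10, written 1-based. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.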

Results

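RNA was sequenced from macrophages taken directly from mouse tumors of the 9609 line, an MCA fibrosarcoma (MCA is the usual short form of the carcinogen methylcholanthrene). The labels define a MEK1-hi group of 3 libraries and a MEK1-low group of 2 libraries. They use these names for the tumor line and its genotype, and also for the exosomes (small vesicles shed by cells) of the treatment. For the MEK1-low group, the exosomes carry the note GFP. The authors' deposited table names its groups by exosome, GFP_exo for MEK1-low and MEK1_exo for MEK1-hi. MEK1 is the kinase that phosphorylates ERK in the RAS-RAF-MEK-ERK cascade and is encoded by Map2k1. The series title speaks of rejecting and growing tumors, but the labels do not say which group is which. The question the design implies is how the macrophages' gene expression differed between the groups, and every direction below is MEK1-hi relative to MEK1-low.

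The authors' deposited table holds 24982 rows with 1 pooled FPKM (a fragment count normalized for transcript length and library size) per group, so no SD can be given. The measure of error is the Cuffdiff test statistic with its q value, which is the adjusted p. Depth per library is unknown from the table. The labels plan for about 25000000 reads per sample. They do not say whether libraries came from separate animals, so Cuffdiff's p and q values measure only the spread between these samples, which may be technical.

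In the MEK1-hi group, most listed transcripts of the interferon-gamma response, antigen presentation, monocytes and dendritic cells were higher. Most of those of resident-like macrophages and fibroblasts were lower. Of 34 gene lists tested with limma's camera, 18 were called (13 higher and 5 lower), and 12 of them also at a preset correlation of 0.05. The correlation between genes could not be estimated without values per library. Camera's p values rest on the spread over genes, not over libraries or animals. Of the 12311 tested rows in the authors' deposited table, 163 were called different at Cuffdiff's q threshold of 0.05. Of these, 123 (75.5%) were higher and 40 (24.5%) lower. The smallest called difference was 0.82 on the log2 scale. Across the 11110 genes of the list tests, the groups' log2(FPKM + 1) values correlated at r = 0.987, a value across genes, which are not independent replicates. The median log2 fold change was -0.02, and rescaling both groups to the same FPKM sum would lower every log2 fold change by 0.13. That shift is smaller than any called difference, and q was not recomputed for it. The count depended on the p values. With p taken from the deposited test statistic and a normal distribution, 15 genes were called, and 0 under the Benjamini-Yekutieli adjustment. An unadjusted p under 0.05 was found in 749 rows of the authors' deposited table (6.08% of those tested). That share is little above what the threshold alone would give.

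**Figure D1:**
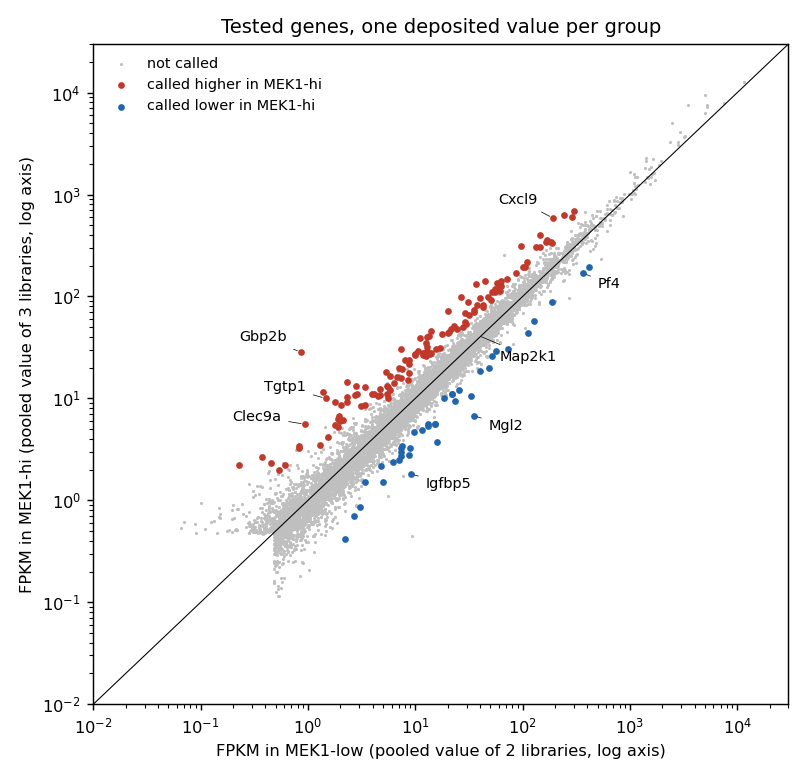
Each point is a tested gene above 0 in both groups, with its deposited FPKM in MEK1-low (pooled over 2 libraries) on the x axis and in MEK1-hi (pooled over 3 libraries) on the y axis, both on log scales, with the line of equality. Red points are genes called higher in MEK1-hi and blue points genes called lower, at q under 0.05; Gbp2b lies farthest above the line, at 0.856 and 28.4 FPKM.

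In the macrophages, MEK1 transcript itself did not pass the test. The labels tie the name MEK1-hi to the tumor line and the exosomes. Macrophage transcripts therefore do not measure that difference, nor the activity of the kinase. In the authors' deposited table, Map2k1 (mm10 chromosome 9, 64185769 to 64253605) had 38.4 FPKM in MEK1-low and 41.5 in MEK1-hi (q = 0.9998). Map2k2, which encodes MEK2, had 47.2 and 46.7 FPKM there (q = 0.9998). Of the 27 tested genes of the RAS-RAF-MEK-ERK cascade, 0 were called by Cuffdiff, 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Mapk3 and Grb2, the most abundant members, had log2 fold changes of -0.09 and 0.29. The ERK target genes, transcripts induced by the pathway, also had 0 called of 30, with 3 lower and 0 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone. Fos had 720 and 681 FPKM and Junb 639 and 868 in the authors' deposited table. By limma's camera test neither list was called, with adjusted p = 0.875 for the cascade and 0.0702 for the targets. For the targets, alternatives gave 0.0325 to 0.241.

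Interferon-gamma response genes rose together. Of 27 tested members, 22 were called higher and 0 lower over all genes, and 25 were higher when adjusted over the list alone. The median log2 fold change was 1.27, and camera gave an adjusted p of 2.51e-87. Its size depended on the setting, since alternatives ran from 2.26e-109 to 1.77e-13, the last in the rank-based test. Among the members are GTPases that act against intracellular pathogens. In the authors' deposited table, Gbp4 went from 7.30 to 30.7 FPKM (statistic 5.19, q = 0.00676), Igtp from 26.8 to 98.5 (4.66, q = 0.00676), Gbp2 from 97.4 to 316 (4.06, q = 0.00676) and Iigp1 from 30.9 to 87.6 (3.91, q = 0.00676). The chemokines Cxcl9 and Cxcl10, which attract activated T cells, rose 3.07-fold and 2.10-fold, to 587 and 604 FPKM in the authors' deposited table. Among called genes, the 5 largest gains of FPKM were those of Cxcl9, Cxcl10 and Fcgr4, completed by Ly6a (300.1 to 682) and AW112010 (241 to 635), as the authors' deposited table gives them. Nos2, the inducible nitric oxide synthase, rose 3.46-fold, and Cd274, which encodes PD-L1, 2.02-fold. Gbp2b, outside the list, had the largest log2 fold change among genes that met the naming rule, 5.05, from 0.856 to 28.4 FPKM in the authors' deposited table (chromosome 3, 142594847 to 142619176, statistic 7.97, q = 0.00676). Near it were Apol6 (3.31), Ubd (3.04), Gpr33 (2.81), Tgtp1 (2.78) and Cd300e (2.63), all called by Cuffdiff. C1s1 (2.22), Gm4841 (2.37) and Klra17 (2.39) completed the 10 largest with Clec9a. Fold changes of Apol6, Ubd, Gpr33, Tgtp1, Gm4841, Clec9a, Gbp2b and, among genes named further on, Tbx21, Lyve1, Thbs4 and Acan shrank by more than 1.5 times with a pseudocount of 1, because their FPKM was low in the lower group. Gbp and Tgtp genes have near-identical copies, so the authors' read assignment could shift values between copies.

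Type I interferon response genes moved far less. Cuffdiff called 0 of 36, 0 passed when adjusted over the list alone, and 2 were higher and 1 lower at an unadjusted p under 0.05. The median was 0.15, or 0.02 after rescaling to equal FPKM sums. Bst2 had 437 and 501 FPKM and Ifi27l2a 284 and 326 in the authors' deposited table. The camera call was marginal (adjusted p = 0.0438), was lost at a preset correlation of 0.05 (adjusted p = 0.192), and ran from 0.00538 to 0.192 over the alternatives. The medians of the interferon-gamma and type I lists, which share 0 tested genes, differed by 1.12, and a two-sided permutation test over their genes gave p = 1e-05, the smallest that 100000 permutations can give. Genes are not independent replicates in that test.

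Antigen presentation genes were higher. For MHC class II, 4 of 15 tested members were called higher, 0 lower, and 9 were higher when adjusted over the list alone (median 0.88, camera adjusted p = 9.49e-17). Ciita, the transactivator of class II genes, rose 2.41-fold, H2-DMb1 2.12-fold, H2-Oa 2.32-fold and the costimulator Cd40 1.85-fold. Ciita is also on the interferon-gamma list. Outside the naming rule, the class II chain genes H2-Aa (q = 0.82), H2-Ab1 (q = 0.357) and H2-Eb1 (q = 0.471) were higher but not called by Cuffdiff. H2-Aa went from 5032 to 9530 FPKM in the authors' deposited table. For MHC class I, 7 of 21 were called higher, 0 lower, and 12 were higher when adjusted over the list alone (median 0.71, adjusted p = 5.2e-19). The peptide transporter genes Tap1 and Tap2 rose 2.07-fold and 1.83-fold, and the proteasome genes Psmb9 and Psme2 1.93-fold and 2.91-fold. The class I genes H2-K1 (q = 0.85) and B2m (q = 0.9998), outside the naming rule, were higher but not called by Cuffdiff.

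Monocyte transcripts were called higher in 6 of 29 and lower in 0, with 8 higher and 1 lower when adjusted over the list alone (median 0.45, camera adjusted p = 5.88e-10). Of the 29, 22 lay above 0 and 7 below, and their summed FPKM was 3286 in MEK1-low and 3379 in MEK1-hi. Outside the naming rule, Ccr2 went from 44.3 to 59.6 FPKM and Vcan from 19.0 to 11.5, neither called over all genes. Ly6c2, a marker of inflammatory monocytes, rose from 31.5 to 65.3 FPKM and Plac8 from 111 to 217 in the authors' deposited table. Ace and Treml4, markers of nonclassical monocytes, rose 2.34-fold and 2.45-fold. Of 34 dendritic cell genes, 6 were called higher and 1 lower, with 10 higher and 2 lower when adjusted over the list alone (median 0.26, adjusted p = 8.96e-10). The higher ones included Clec9a (2.58 on the log2 scale), Cadm1 (2.75-fold), Naaa (2.06-fold) and Kit (2.65-fold), of which Clec9a and Cadm1 mark cross-presenting dendritic cells. The member called lower was Ccl17, which went from 15.9 to 3.73 FPKM in the authors' deposited table. Of the 34, 25 lay above 0 and 9 below. Phagocytosis and Fc receptor genes were not called as a list (2 of 26 called higher, 0 lower, 3 higher adjusted over the list alone, adjusted p = 0.164). Its called members were Fcgr4, which went from 145 to 405 FPKM, and Timd4, from 2.29 to 9.13, in the authors' deposited table.

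NK and cytotoxic cell markers were higher, most of them at low levels (median 4.66 FPKM in MEK1-hi). Of 13 NK and cytotoxic cell genes, 3 were called higher and 0 lower, and 9 were higher when adjusted over the list alone (median 1.25, camera adjusted p = 9.49e-17). Klrk1 went from 5.27 to 18.1 FPKM, Tbx21 from 0.825 to 3.42 and Ccl5 from 184 to 342 in the authors' deposited table. Of 22 T cell genes, 0 were called higher and 1, Thy1, lower, with the same counts when adjusted over the list alone (median 0.06, adjusted p = 0.794). Of the 22, 13 lay above 0 and 9 below. Outside the naming rule, Cd3e went from 0.889 to 1.74 FPKM, Cd3g from 2.07 to 3.64 and Cd8a from 1.15 to 2.88. Cd4 went from 27.8 to 19.3 FPKM in the authors' deposited table, and none of these was called. T cells are thus not shown to be equal between the groups. Thy1 is also made by fibroblasts and is on that list too.

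**Figure D2:**
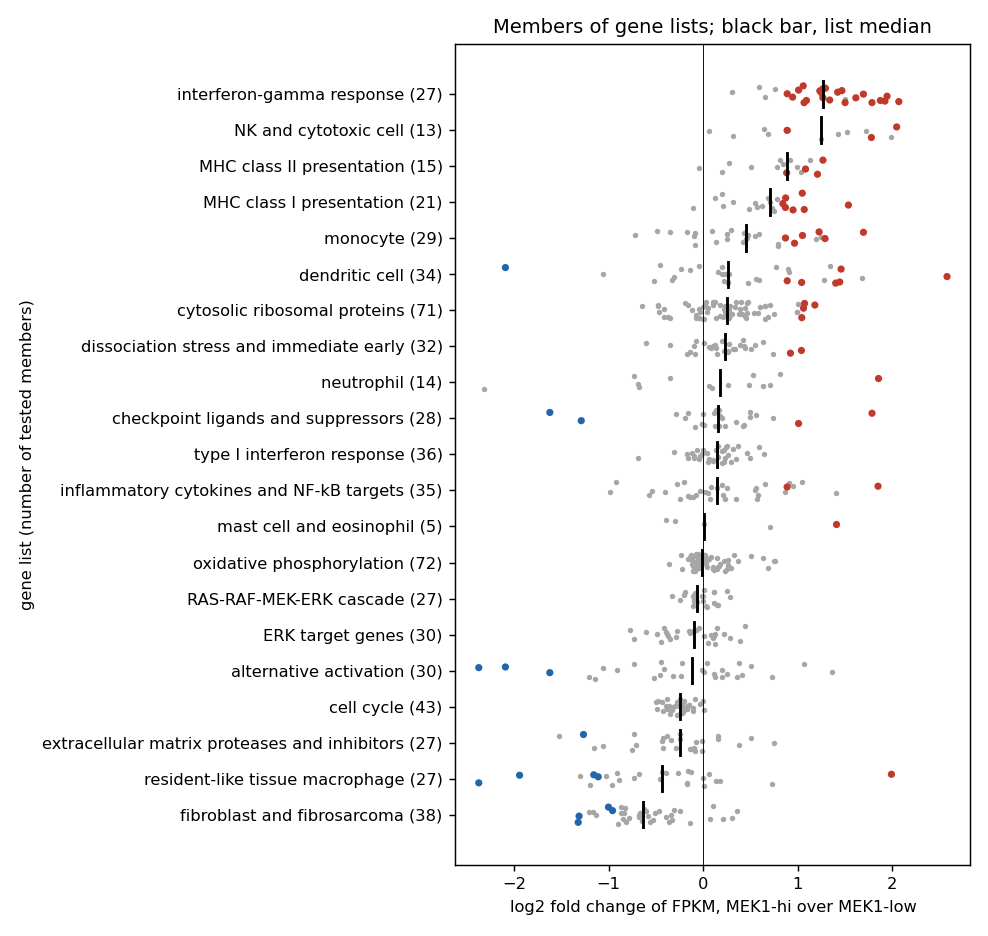
Points are the tested members of each gene list (number in brackets), placed by the log2 fold change of FPKM in MEK1-hi over MEK1-low; red and blue points were called higher and lower at q under 0.05, grey points were not called, and the black bar is the list's median. The 18 lists called by camera are shown with 3 that were not (ERK targets, the RAS-RAF-MEK-ERK cascade and oxidative phosphorylation); medians run from -0.64 for fibroblast genes to 1.27 for interferon-gamma response genes, and rescaling to equal FPKM sums shifts all of them by 0.13, which turns the mast cell median (0.01) below 0.

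Most resident-like genes were lower, and 3 genes of alternative activation were called lower. Of the 30 tested on the alternative activation list, 16 lay below 0 and 14 above, and 3 were called lower and 0 higher, with 6 lower and 3 higher when adjusted over the list alone (median -0.12, camera adjusted p = 0.00696). This list's call was lost at a preset correlation of 0.05 (adjusted p = 0.0762) and in the rank-based test (0.458), and its lowest value over the alternatives was 0.000171. Arg1, the arginase that competes with nitric oxide synthase for arginine, went from 32.8 to 10.6 FPKM (statistic -3.58, q = 0.00676), the lectin gene Mgl2 from 35.1 to 6.76 (-4.79, q = 0.00676) and the chemokine gene Ccl17 from 15.9 to 3.73 (-2.64, q = 0.0276) in the authors' deposited table. Of 27 resident-like genes, 4 were called lower and 1 higher, with 9 lower and 2 higher when adjusted over the list alone (median -0.44, adjusted p = 2.46e-08). Of these 27, 21 lay below 0 and 6 above, and their summed FPKM was 4264 in MEK1-low and 4308 in MEK1-hi. Outside the naming rule, Ccl8 went from 999 to 1659 FPKM and Folr2 from 67.4 to 67.8, neither called over all genes. Pf4 went from 366 to 169 FPKM and Cbr2 from 128 to 57.5 in the authors' deposited table. Timd4 was the member called higher, and Lyve1, also an endothelial gene, fell by 1.94 on the log2 scale. The 5 largest losses of FPKM among called genes also included Fcrls (415 to 196), Ms4a4a (187 to 88.8) and Tnc (113 to 44.1), as the authors' deposited table gives them.

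Fibroblast and fibrosarcoma transcripts, markers of the tumor and its stroma rather than of macrophages, were lower. Of 38 tested members, 4 were called lower and 0 higher, with 12 lower and 0 higher when adjusted over the list alone (median -0.64, camera adjusted p = 6.35e-18). Acta2 went from 23.4 to 9.36 FPKM, Col6a3 from 49.0 to 19.7, Thy1 from 51.8 to 25.8 and Col5a1 from 56.6 to 29.1 in the authors' deposited table. Extracellular matrix proteases and inhibitors had 1 of 27 called lower, Ctsk (73.5 to 30.5 FPKM in the authors' deposited table), with 5 lower and 1 higher when adjusted over the list alone (median -0.25, adjusted p = 0.000123). The 10 smallest log2 fold changes also held the matrix genes Thbs4 (-2.39) and Acan (-1.83) and the proteoglycan gene Cspg4 (-1.73), with Igfbp5 (-2.33), Lrrc15 (-1.67) and Atp6v0d2 (-1.49). Cell cycle genes had 0 of 43 called by Cuffdiff, 0 adjusted over the list alone and 1 lower at an unadjusted p under 0.05, yet 41 of 43 lay below 0 (median -0.24, adjusted p = 1.06e-05). Cenpa and Pcna, its most abundant members, had log2 fold changes of -0.21 and 0.00.

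Cytosolic ribosomal protein genes had 4 of 71 called higher and 0 lower, with the same counts when adjusted over the list alone (median 0.25, or 0.12 after rescaling to equal FPKM sums, camera adjusted p = 2.09e-07). Among them, Rpl23, Rplp2 and Rpl21 rose between 2.09-fold and 2.27-fold. Many ribosomal protein genes have pseudogene copies, and their FPKM ranged from 0.875 to 1647 (mean of both groups), so these values are uncertain. The dissociation stress list, a sign of tissue handling, had 2 of 32 called higher, Jund (2.06-fold) and Hspa1b (1.90-fold), with the same count when adjusted over the list alone (median 0.23, adjusted p = 0.000148). Hspa1b has a near-identical neighbor. Fisher's exact test of called members did not pass for the dissociation list (adjusted p = 0.173) or the ribosomal list (0.053). For the extracellular matrix proteases and inhibitors it did not pass either (adjusted p = 0.549).

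Some lists were called only under part of the settings. Cytokines and NF-kB targets had 2 of 35 called higher, Acod1 (36.5 to 132 FPKM in the authors' deposited table) and Ccl5, with 2 higher and 1 lower when adjusted over the list alone (median 0.15, camera adjusted p = 0.0141). At a preset correlation of 0.05 its adjusted p was 0.117, and alternatives ran from 0.00343 to 0.117. Checkpoint ligands and suppressors had 2 of 28 called higher (Cd274, Nos2) and 2 lower (Arg1, Nt5e), with the same counts when adjusted over the list alone (adjusted p = 0.0487, 0.192 at a preset correlation of 0.05, alternatives 0.0145 to 0.486). Neutrophil genes had 1 of 14 called higher, Acod1, which interferon-activated macrophages also make, with 3 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0438, 0.122 at a preset correlation of 0.05, alternatives 0.00856 to 0.422). Mast cell and eosinophil genes had 1 of 5 called higher, Kit, with 2 higher when adjusted over the list alone (adjusted p = 0.0438, 0.0797 at a preset correlation of 0.05, alternatives 0.0227 to 0.812). The chemokine list was not called as a whole by camera (adjusted p = 0.883). Of 33 members, Cxcl9, Cxcl10 and Ccl5 were called higher and Ccl17 and Pf4 lower. Adjusted over the list alone, 4 were higher and 3 lower. Fisher's exact test, which ignores direction, found a larger share of called members than among the other genes (adjusted p = 0.00047). It did so for the checkpoint list too (adjusted p = 0.00269).

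The remaining lists were not called by camera. Complement and lipid-associated macrophage genes had 0 of 29 called by Cuffdiff, with 3 higher at an unadjusted p under 0.05 and when adjusted over the list alone (adjusted p = 0.472). Apoe had 11456 and 12566 FPKM in the authors' deposited table. Cuffdiff called 0 of 72 oxidative phosphorylation genes (2 higher and 0 lower at an unadjusted p under 0.05), 0 of 38 hypoxia and glycolysis genes (1 and 0), 0 of 23 cholesterol biosynthesis genes (0 and 1), 0 of 29 unfolded protein response genes (0 and 2) and 0 of 29 exosome machinery genes (0 and 0), and none of these passed when adjusted over the list alone. Their camera adjusted p values were 0.565, 0.372, 0.751, 0.954 and 0.532. For other cell types, Cuffdiff called 0 of 10 B and plasma cell genes (0 higher and 2 lower at an unadjusted p under 0.05), 0 of 6 epidermis genes (0 and 0), 0 of 5 muscle and adipocyte genes (1 and 0) and 0 of 5 erythroid genes (0 and 0), and 0 of each when adjusted over the list alone. Their adjusted p values were 0.603, 0.878, 0.472 and 0.24. Endothelial genes had 1 of 14 called lower, Lyve1, and 2 when adjusted over the list alone (adjusted p = 0.404). Median, mean and test differed in sign for the complement, phagocytosis, oxidative phosphorylation, B cell, epidermis and unfolded protein lists. Histones and sex-linked genes had 4 tested members each, too few for the list test, and Cuffdiff called 0 of both, with 0 at an unadjusted p under 0.05.

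**Figure D3:**
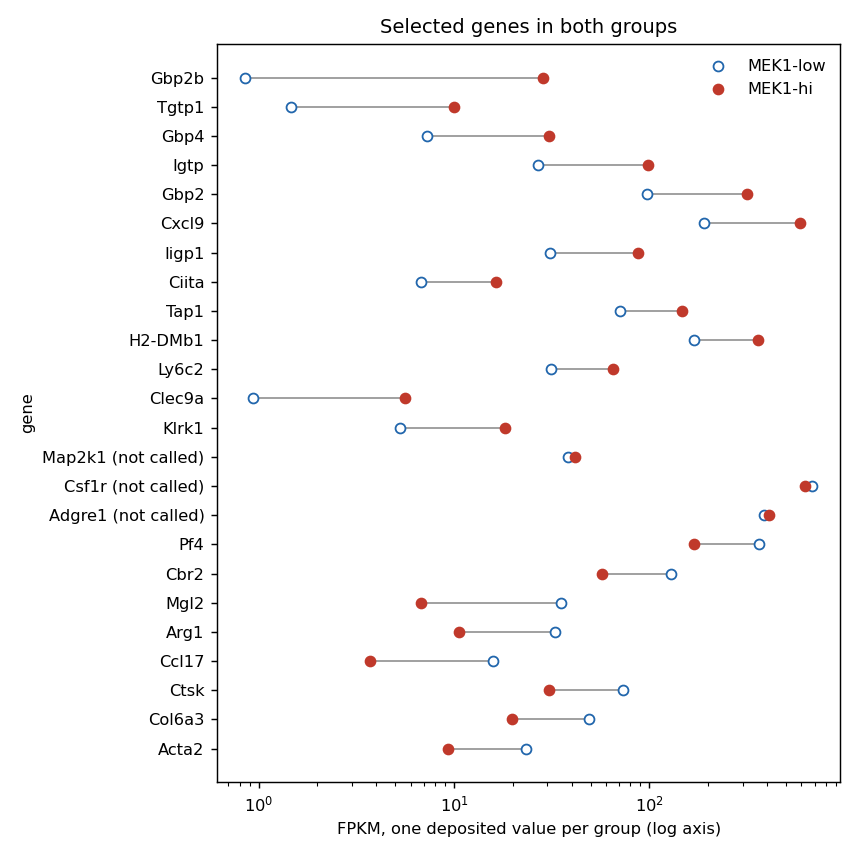
FPKM of 24 genes in the authors' deposited table, on a log axis, with open circles for MEK1-low and filled circles for MEK1-hi; each circle is 1 pooled value without an error bar. Interferon-gamma and antigen presentation genes such as Cxcl9 (191 and 587 FPKM) are higher in MEK1-hi, Mgl2 (35.1 and 6.76) and Pf4 (366 and 169) are lower, and Map2k1 with the macrophage markers Csf1r and Adgre1, chosen after their values were seen, were not called.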

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

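In the authors' deposited table, 2 rows share a locus (mm10 chromosome 4, 43442277 to 43454626) on which the authors' test failed, so neither enters a comparison above. Cd72, a receptor of B cells and some myeloid cells, had 286 FPKM in MEK1-low and 493 in MEK1-hi there (1.72-fold higher in MEK1-hi). Tesk1 had 17.8 and 20.03 FPKM in the same table. Neither difference was tested. The joint row of Cd74 and Mir5107 had too much data for Cuffdiff and is listed at 0 in MEK1-hi against 9984 FPKM in MEK1-low in the same table, so its second value is a missing estimate.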

How the results depend on the processing

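The alternatives named last for lists, the one without interferon-gamma genes and the one for transcript length, were chosen after seeing the data. No paired analysis was possible because the table gives 1 value per group, and leaving out each library was not run for the same reason. The 163 called genes (123 higher, 40 lower) became 91 (68 higher, 23 lower) at a q threshold of 0.01, which calls fewer by construction. Taking p from the deposited test statistic with a normal distribution left 15 (13 higher, 2 lower, Mgl2 and Igfbp5). The Benjamini-Yekutieli adjustment left 0 (0 higher, 0 lower), because the smallest p is 5e-05. Counts stayed within 1.5 times at a q threshold of 0.1 (198), with a 2-fold minimum (138), with an FPKM filter and new adjustment (173, which holds 162 of the 163), and without rows of several or repeated symbols (160). Both scalings shift all genes alike by less than any called difference, so they could turn no call and say nothing of stability. Of the 34 tested lists, 18 were called, and between 12 (preset correlation 0.05) and 19 (preset correlation 0) under the alternatives. Of the called lists, 0 changed direction; 6 lists that were not called did, under at least one alternative. Calls under every setting that tested them were made for 12 lists; with no FPKM filter 17 were called, and 14 with a filter of 5, with log2(FPKM + 1) differences, after rescaling, and by ranks. Leaving out the interferon-gamma genes, 16 of 33 lists were called, and with the median statistic of genes of like length subtracted, 16 of 34, of which 15 are among the 18. Of the named genes' 408 values under other pseudocounts and scalings, 11 moved by 1.5 times or more, all with a pseudocount of 1, and 0 called genes changed sign; 6 uncalled genes turned negative after rescaling. Unknown depth and 2 and 3 libraries per group limit what could be called, and a gene that was not called is not shown to be equal.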

Other observations

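Of the tests below, those of chromosomes, scaling, T and NK cells, monocytes, the stromal share, pseudogenes and length as the whole of the ribosomal rise were chosen after the results were seen. The remaining length tests were set before theirs were seen.

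The gene groups in this paragraph were put together after their values were seen, so they are described without a test. Of 12 immunity-related GTPases and related gene models (Irgm1, Igtp, Tgtp2 and others), 11 were called higher and 11 lay above 0. Among 9 guanylate-binding protein genes, 7 were called higher and 9 lay above 0. Klr lectins, a gene family that includes receptors of NK cells, had 4 of 9 called higher (Klra2, Klrb1b, Klrk1, Klra17) and 9 above 0. The complement genes C4b, C1s1 and C2 were called higher, while the far more abundant C1q genes were not called (C1qa had 3261 and 3758 FPKM in the authors' deposited table) and the fixed complement list had 0 of 29 called. Collagen chains had 5 of 21 called lower and 20 below 0, or 21 after rescaling to equal FPKM sums. H2 genes had 3 of 22 called higher and 22 above 0, also after rescaling. Many of these genes are on the fixed lists too. No chromosome held more called genes than the rest by Fisher's exact test (lowest adjusted p = 0.215 over all chromosomes).

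Other genes, chosen after their values were seen, stand near these. Il4, the cytokine that drives alternative activation, was the 1 called gene at 0 in a group. The authors' deposited table gives 0.603 FPKM in MEK1-low and lists it at 0 in MEK1-hi (q = 0.00676). Il4 has no usable test statistic there. It lay under 1 FPKM in both groups and is the 1 call lost with the FPKM filter, so this call is weak. Ifng itself had 0.347 and 1.15 FPKM (q = 0.548), Cd8a 1.15 and 2.88 (q = 0.202) and Il12b 2.48 and 5.12 (q = 0.262) in the authors' deposited table, none called. The macrophage markers Csf1r (680 and 628), Adgre1 (388 and 411) and Cd68 (785 and 741 FPKM) were not called there either.

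The interferon-gamma genes were higher by a median of 1.27. A difference in scaling would move all genes alike, but the other tested genes had a median of -0.0213. Against carried-over T cells, whose markers had a median of 1.88 FPKM in MEK1-hi, stands the list's median gain of 25.0 FPKM. That gain stands against carried-over NK cells too: 18 NK markers and Klr genes gained a median of 2.65 FPKM (to a median of 5.75). Some of these Klr genes may be made by other cells. Among the 18, Ccl5, which macrophages also make, gained 157 FPKM, Klra2 78.4 and Klrb1b 27.04, and the other 15 at most 12.9. More monocytes in the MEK1-hi preparation cannot be told apart from a response of the same cells. The monocyte markers had a median of 0.45, and the share of each cell type was not measured. The dendritic cell list was called higher too (median 0.26). Whether the MEK1-hi preparation held more dendritic cells was not tested. An effect of the MEK1-hi tumor or exosomes, or of NK or T cells on the macrophages, stays open and untested.

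Lower fibroblast and matrix genes may reflect a smaller share of fibroblasts or tumor cells in the MEK1-hi preparation. Such a share would lower markers of these cells that encode no matrix or secreted protein as much as the rest: the 14 such members of the list had a median of -0.65 (12 lower, also after rescaling to equal FPKM sums; Twist1 and Twist2 higher), against -0.63 in the other 24. Transcript length is a weaker candidate: log2 fold change fell with length across genes (Spearman rho -0.249 over 10970 genes, which are not independent), but removing the median of genes of like length left the list at -0.59 of -0.64. Lower expression of these genes within the same cells, or a stroma that differs between the groups, stays open.

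For the ribosomal protein genes, a correction for length removed part of the rise. Removing the median of genes of like length left 0.18 of 0.25, so a contribution of length stays open. The list was still called by camera on length-corrected statistics (adjusted p = 0.000101), which argues against length as the whole of the rise. Lengths were those of the longest transcript per symbol, so the correction may be incomplete and does not exclude length. Reads lost to pseudogenes would spare the more abundant genes, whose median was 0.31 (31 of 35 higher, or 25 after rescaling) against 0.16 in the other 36. The tumor or exosome group stays open as an untested explanation.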
